A study of Homo sapiens with 24 samples.

How the data were processed

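Methylation of genomic DNA was profiled in 24 libraries of human dorsolateral prefrontal cortex, a part of the frontal lobe. Per the labels, the tissue was frozen, homogenised and not separated by cell type, and DNA was taken up with a column kit. Libraries were made by reduced representation bisulfite sequencing, per the labels' protocols, and sequenced on an Illumina Genome Analyzer IIx. In this assay a restriction enzyme that cuts at CCGG sites enriches CpG-rich DNA, and bisulfite turns unmethylated cytosines into bases read as thymine. A cytosine that still reads as cytosine counts as methylated. All 24 libraries carry the same label, control, so they form 1 group and no groups could be compared. The labels do not state outright that each library comes from a different donor. At the 2555 positions whose levels behaved like those of sequence variants (defined with the alternatives), deviations correlated between library pairs by −0.194 to 0.142. No pair of libraries looked like 1 sample deposited more than once.

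The deposited tables list, for each library, the cytosine positions of CpGs with a read count and a percent of methylated reads. The read counts in the deposited tables are whole numbers from 1 up. The percent values are rounded by the authors to whole percents, as the values show, and 100% of them equal the rounded ratio of a whole number of methylated reads to the count, after rounding to the nearest percent. Methylated reads were recovered from this ratio. At counts over 100 any whole percent passes this check. More than 1 number of methylated reads can then give the same percent, so the recovered number is approximate there. The strands of a CpG are listed as separate positions, so a level here belongs to 1 cytosine. Positions refer to build hg19, per the submitters' processing notes. The aligner, the caller and the filters on reads are not given in the sources used here. Whether positions count from 0 or from 1 is not given either, so coordinates are printed as listed and may lie 1 base from those of a genome browser.

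The autosomes were used. The sex chromosomes were left out on reading, because the donors are people, and mitochondrial positions were kept apart. A level was used where at least 10 reads covered the position in that library, and a position was used where at least 20 of the 24 libraries reached that minimum. The minimum was set before the data were examined. This left 726934 positions, with a median of 48 reads per position in the median library. At 48 reads, 24 of them methylated, a level of 50% has a 95% Wilson interval from 36.4% to 63.6%. Reads carry no molecular identifiers, so intervals cover counting error only.

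Positions were called low under 20%, intermediate from 20% to 80% and high over 80%, by the mean over libraries. CpG density was the number of CpGs listed in any library in the 200 bases around a position, since no sequence of the build was used here. Density classes were compared within libraries by a two-sided sign-flip permutation test with 100000 resamples, whose smallest p is 1e-05. Relations over libraries were given as Pearson's r and Spearman's rho with two-sided permutation p-values from 100000 resamples and Benjamini-Hochberg adjustment. For joint variation with distance, intermediate positions had their own mean and then the library mean subtracted.

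The planned tests by gene, promoter and gene list were not run. The gene table at hand describes another assembly, GRCh38.p14, coordinates were not moved between builds, and no gene names were attached to positions. The lists of brain cell markers, imprinted genes and other genes fixed in advance therefore gave no values, and relations between cell type lists were not computed. In place of promoters, regions were formed from used positions at most 100 bases apart, with at least 5 positions. This substitution was made after the tables had been seen. Reads of a region were pooled per library where at least 80% of its positions reached the minimum. The spread between libraries was tested by a chi-square against a beta-binomial variance. The effective depth was the mean reads per position, because close cytosines can lie on the same reads. Cytosines taken as covered by the same reads spanned at most 34 bases, and regions had a median span of 84 bases. Where a region holds more than a single set of reads, this depth is too small and the null variance too large. The test is then conservative and can miss spread. The within-library correlation of reads, 0.00361, came from strand differences at 5843 intermediate CpGs, where the variance was 1.12 times the binomial value. Regions were called variable at an adjusted p under 0.05 over all tested regions and an SD of at least 5 percentage points.

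The procedure was tested on simulated data. Among 42626 simulated regions without spread between donors, 4 were called and 5.62% had an unadjusted p under 0.05. These reads were drawn from the model of the test, with its own correlation and effective depth, so those assumptions were not checked. Of 200 regions given a spread with an SD of 20 points, 98% were recovered, against 45% at 10 points and 1% at 5 points. A strand correlation simulated at 0.02 was estimated at 0.0202.

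Named regions follow the rule fixed in advance for promoters. They are the 10 variable regions with the largest SD that were still called without the 2 libraries farthest from the median, the 10 regions of at least 20 positions with the highest mean, and the 10 of at least 20 positions with a mean from 40% to 60% and the smallest SD. The parts of the rule that draw on gene lists could not be applied. Quartiles are printed instead of the values of single donors.

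Cytosines with equal read counts in all 24 libraries, lying within 100 bases, were taken as covered by the same reads. The 93547 such sets of at least 3 cytosines with a strand span at most 34 bases, and their order from the read start follows from the strand. In sets of at least 4 cytosines the first was compared with the second, and the set was classed by its later cytosines only. An earlier form of this comparison classed sets by cytosines that were also compared, and was replaced because that choice biases the difference. The first cytosine still lies farther than the second from the cytosines that class the set, which can also bias the difference.

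Settings varied as fixed in advance were minima of 5 and 20 reads, other limits for the classes and other sets of positions. For regions they were a binomial null, leaving out the 2 farthest libraries, and leaving out variant-like positions. A position was variant-like at an SD of at least 10 points with every level within 15 points of 0, of its own upper level (the 95th percentile over libraries, at least 60%) or of the midpoint between them. Settings chosen after seeing the data were leaving out the first and last cytosines of reads, averaging deviations from position means, and removing the mean of each of 2 sets of libraries defined in the report. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.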

Results

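Cytosine methylation was measured at CpGs of the autosomes in 24 libraries of bulk dorsolateral prefrontal cortex, all labelled control. With 1 group, the values describe control cortex, its spread between libraries and differences between kinds of position within libraries. A library held 49522066 ± 8520052 reads summed over its positions (SD, n = 24), from 34936216 to 69024110. It reached 10 reads at 866737 ± 85930 positions (SD, n = 24), from 668020 to 1050146. Levels of library pairs correlated across positions by 0.976 to 0.987, where positions are not independent replicates.

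Most CpGs covered deeply enough to be used carried little methylation in this cortex. Of 2058772 autosomal positions listed in any library, 726934 were used. The others were not classed, and the library mean was higher with no minimum of reads, at 31.4% against 23.6%. Of the 726934 used positions, 75.2% had a mean level under 20%, 10.3% lay between 20% and 80%, and 14.5% lay over 80%. The median level was 1.27% in the low class, 50.5% in the intermediate class and 94.6% in the high class. In single libraries, 75.5 ± 0.677% of positions were low and 14.2 ± 0.654% were high (SD, n = 24). The distribution had its peaks at both ends, with 64.0% of positions under 5% and 6.71% at 95% or more.

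**Figure D1:**
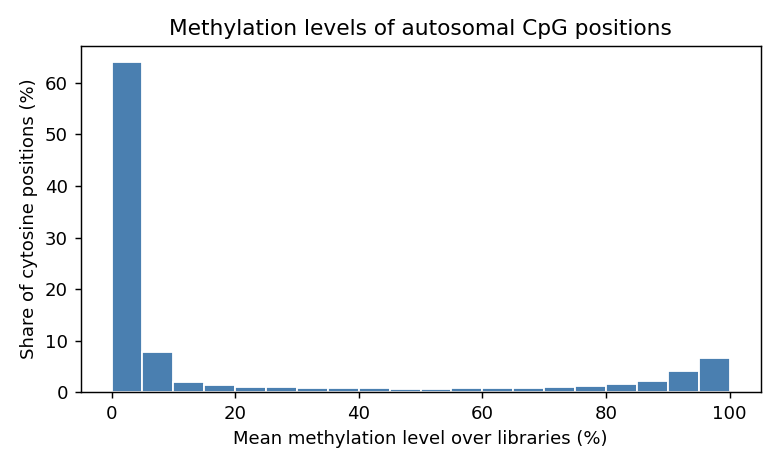
The bars give the share of autosomal cytosine positions, in percent, by their mean methylation level over 24 libraries, in bins of 5 percentage points. The lowest bin holds 64.0% of the positions and the highest bin 6.71%.

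The library mean over its own positions was 23.6 ± 1.44% (SD, n = 24), from 19.9% to 25.9%. Over the 548447 positions measured in every library it was 16.7 ± 0.609% (SD, n = 24), from 15.7% to 17.9%. The spread between libraries at single positions was small in the low class, with a median SD of 1.76 percentage points, and larger in the intermediate class, with a median of 10.3 points. It was 4.35 points in the high class. An SD between libraries under 5 points was found at 78.9% of positions.

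Methylation fell steeply where the CpGs listed in any library were dense. CpGs that no library listed were not counted, so sparse can also mean few covered sites nearby. Positions with 1 to 3 CpGs in the surrounding 200 bases averaged 74.1 ± 1.93% (SD, n = 24), positions with 4 to 9 CpGs averaged 47.8 ± 1.40%, and positions with 10 or more averaged 7.34 ± 0.499%. The sparse class exceeded the dense class by 66.8 ± 1.56 points (SD, n = 24) and did so in 24 of 24 libraries. The sparse class also exceeded the middle class by 26.3 ± 0.796 points, and the middle class exceeded the dense class by 40.4 ± 0.9991 points, in 24 of 24 libraries each. All 3 differences reached the smallest p that the permutation test can give (two-sided, p = 1e-05, adjusted p = 1e-05). In the dense class 92.2% of positions were low, and in the sparse class 61.8% were high. The p-values ask whether these libraries share a direction of difference at the same positions, and do not measure its size.

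**Figure D2:**
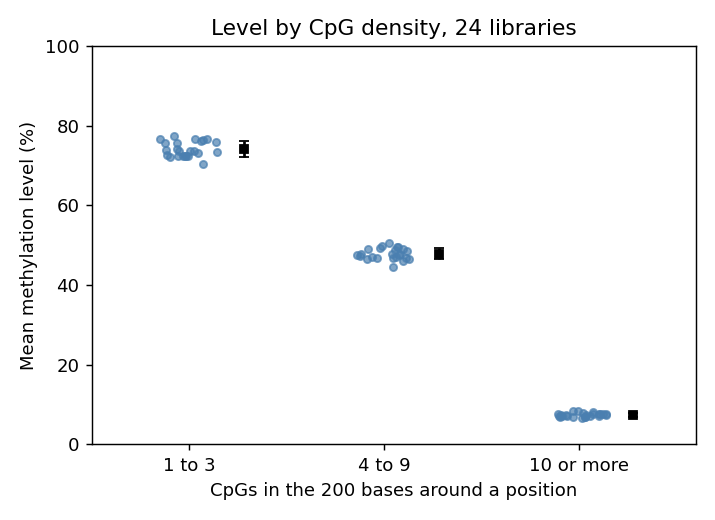
Each point is the mean methylation level of 1 library, in percent, over positions with the number of listed CpGs in 200 bases given on the horizontal axis; squares with bars are the mean and SD of 24 libraries. The classes average 74.1%, 47.8% and 7.34% and do not overlap.

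Stretches of intermediate methylation were counted as runs. Runs of at least 5 consecutive measured positions within 500 bases, each with a mean level from 35% to 65%, numbered 953 and held 6318 positions. Of these runs, 86 had at least 10 positions, and 44 overlapped a region called variable between libraries. Such runs were to be counted in imprinted genes, which carry methylation on 1 parental allele, but no genes were attached to them. At a minimum of 5 reads 1270 runs were found, at 20 reads 510, and 515 without the first and last cytosines of reads.

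Among regions with at least 20 positions, 68 had a mean from 40% to 60%, and 3 of them were called variable. The 10 steadiest of them had SDs from 3.65 to 4.58 points. The region with the smallest SD lay on chromosome 9 from 140263231 to 140263635 and averaged 59.5 ± 3.65% over 34 positions (SD, n = 22). A region on chromosome 12 from 2339316 to 2339595 averaged 46.8 ± 3.65% (SD, n = 21), and one on chromosome 5 from 172175550 to 172175909 averaged 40.2 ± 3.799% (SD, n = 24). On chromosome 17, the region from 44896865 to 44897024 averaged 49.1 ± 4.02% (SD, n = 24). On chromosome 1, the region from 40769263 to 40769617 averaged 54.7 ± 4.05% (SD, n = 24). The region of chromosome 11 from 2720952 to 2721086 averaged 40.9 ± 4.30% (SD, n = 23), and that of chromosome 20 from 57430915 to 57431144 averaged 41.8 ± 4.33% (SD, n = 24). Chromosome 22 held 2 of the 10 regions, at 51159188 to 51159805 with 44.6 ± 4.32% over 52 positions (SD, n = 23) and at 50117939 to 50118247 with 56.8 ± 4.58% (SD, n = 23). The last, on chromosome 10 from 127584487 to 127584810, averaged 53.6 ± 4.33% (SD, n = 21) at a median of 269 reads per position, against 27.1 to 78.2 reads in the other 9 regions. Adjusted p was 1 in the beta-binomial test for each of the 10, which does not show that they are equal in all donors. The 10 were chosen for the smallest SDs, and the test gives these long regions only the mean depth of a position. This outcome was therefore nearly fixed in advance.

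The regions with the highest methylation were nearly fully methylated. The 10 highest among regions of at least 20 positions averaged from 97.4% to 98.2%. The highest lay on chromosome 8 from 144991267 to 144991391 and averaged 98.2 ± 0.361% over 22 positions (SD, n = 24). It was followed by a region of chromosome 22 from 46610267 to 46610657 at 98.0 ± 0.427% (SD, n = 24) and a region of chromosome 13 from 21562505 to 21562754 at 98.0 ± 0.634% (SD, n = 20). Chromosome 6 held 3 of the 10 regions, starting at 66497721, 168391295 and 169424509, and chromosome 2 held those starting at 3392155 and 121746137. The remaining regions started at 140728751 on chromosome 9 and 179563510 on chromosome 5. By contrast, 8133 of the 9098 tested regions of this size, or 89.4%, averaged under 5%.

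A small share of regions differed between libraries by more than counting error allows in the beta-binomial test. Of 42626 tested regions, 276 were called variable, and 95 of them were still called without the 2 libraries farthest from the median of the region. The called regions had a median SD of 10.7 points and a median level of 53.5%. Of regions with an intermediate mean, 157 of 5527 were called (2.84%), against 76 of 7049 with a high mean (1.08%) and 43 of 30050 with a low mean (0.143%). With a binomial null 447 regions were called. The count of 276 may be low, since the test gives a region the mean depth of a position even where it spans several sets of reads. Simulated spreads with an SD of 5 points at levels from 40% to 60% were recovered in 1% of regions, where the call also requires an SD of at least 5 points.

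The 10 named variable regions had SDs from 20.5 to 32.0 points and adjusted p-values (beta-binomial chi-square, Benjamini-Hochberg) of 3.22e-07 or smaller. The largest SD was on chromosome 19 from 53701038 to 53701096, where 6 positions averaged 57.8 ± 32.0% (SD, n = 20) with quartiles at 32.4% and 93.4%. On chromosome 11 a pair of regions about 1 kilobase apart were both variable. The one from 401705 to 401737 averaged 61.6 ± 28.8% (SD, n = 23), and the one from 400690 to 400750 averaged 37.2 ± 28.2% (SD, n = 21). Chromosome 21 also held a pair, at 47581181 to 47581211 with 71.4 ± 25.2% (SD, n = 24) and at 47581415 to 47581500 with 65.5 ± 24.2% (SD, n = 21). The region of chromosome 12 from 132335888 to 132335942 averaged 68.7 ± 22.6% (SD, n = 21), and the region of chromosome 17 from 15653446 to 15653493 averaged 47.0 ± 22.04% (SD, n = 24). On chromosome 8, the region from 216591 to 216659 averaged 32.97 ± 21.99% at a median of 70 reads per position (SD, n = 24). On chromosome 2, the region from 12054804 to 12054865 averaged 56.0 ± 21.7% at a median of 22.5 reads (SD, n = 23). The region with the most positions, 17, lay on chromosome 19 from 12876916 to 12877064 and averaged 20.2 ± 20.5% (SD, n = 23), with quartiles at 2.03% and 28.2%. At a minimum of 20 reads, 5 of the 10 could be tested, and without the first and last cytosines of reads 6 could be tested. All of those were called. The 10 were chosen for large SDs in the same reads, so being called again is not independent support. Sequence variants between donors can give such spreads and were not typed here.

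**Figure D3:**
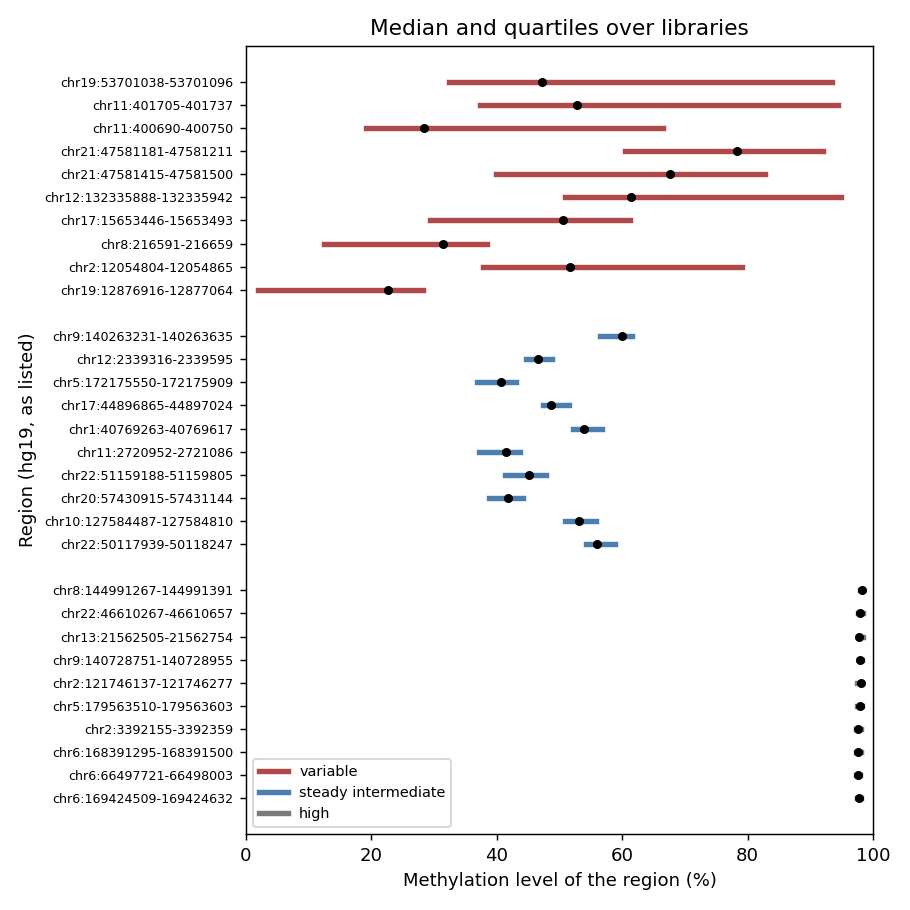
For each named region, the dot is the median and the bar spans the quartiles of the methylation level, in percent, over the libraries measured there. The 10 variable regions are at the top, the 10 steady intermediate regions in the middle, and the 10 highest regions at the bottom, between 97.4% and 98.2% on average.

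Neighbouring CpGs of intermediate level varied together between libraries, and the relation faded over kilobases. Over 74875 intermediate positions, the mean r over libraries was 0.572 for pairs 2 to 10 bases apart and 0.371 for pairs 21 to 40 bases apart, which 1 read can cover. It was 0.213 at 41 to 100 bases, 0.199 at 201 to 500 bases, 0.152 at 501 to 1000 bases and 0.088 at 1001 to 2000 bases. At 5001 to 10000 bases it was 0.0358, and for 188787 pairs on different chromosomes it was −0.000139, a value that subtracting the library mean holds near 0. Pairs of adjacent positions, the 2 strands of 1 CpG, had a mean r of 0.294. Pairs are not independent, so no p was computed. Counting error lowers r for pairs on separate reads, while pairs on the same reads share part of that error, which can raise r.

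**Figure D4:**
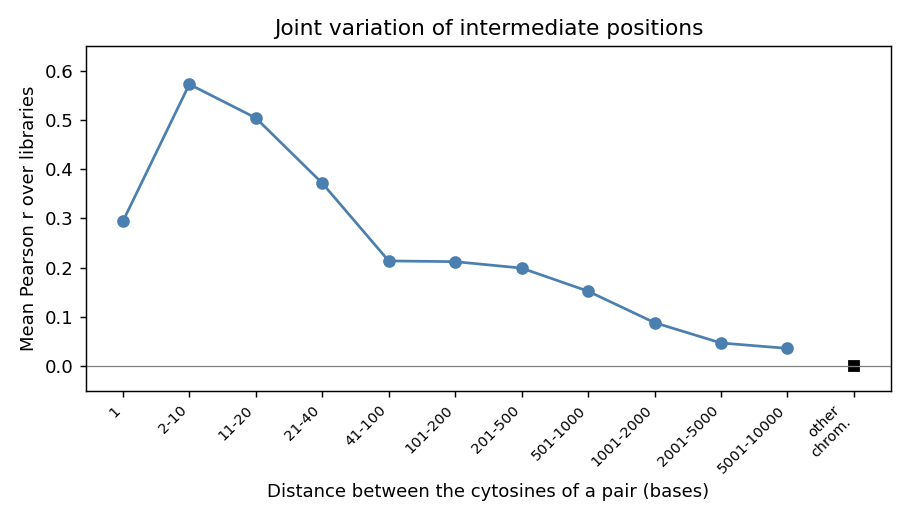
The points give the mean Pearson r over 24 libraries for pairs of intermediate positions, by the distance between them in bases; the square is for pairs on different chromosomes. The mean r is 0.572 at 2 to 10 bases and 0.0358 at 5001 to 10000 bases.

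The strands of a CpG gave nearly equal levels. Over 78483 CpGs with both strands measured, the median difference of the strands within a library was 1.63 ± 0.257 points (SD, n = 24), and the median difference of library pairs at 1 strand was 1.66 points. At 5843 intermediate CpGs the strands differed by a median of 8.10 ± 0.819 points (SD, n = 24), and libraries differed by 9.06 points on average over pairs. At a typical single CpG, libraries differed by little more than the strands of 1 library did. The strand difference can also hold differences between strands that all libraries share, and the difference between libraries at 1 strand holds none. How far libraries differ beyond measurement error can therefore not be read from these values.

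Libraries fell into 2 sets by a technical measure, the difference between the first and the second cytosine of a read. In reads whose later cytosines lay from 30% to 70%, the first cytosine was lower by 5.97 ± 0.911 points in 11 libraries and by 10.2 ± 0.858 points in 13 libraries (SD). The widest gap between libraries, 1.43 points, separated these sets. The sets also did not overlap in reads whose later cytosines lay under 2%, where the first cytosine was higher by 4.87 ± 0.663 points in the 11 libraries and by 1.95 ± 0.563 points in the 13. The labels name no batch, but in the order of the submitters' library numbers, which is also the order of the samples in the series, the sets formed 4 blocks, against 12.9 on average in random orders (one-sided permutation test chosen after seeing the data, p = 1e-04). With the mean of each set removed, 228 regions were called variable, 225 of them among the 276, and the 10 named variable regions were all called.

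Deeper libraries had higher mean levels over their own positions, but not over positions measured in every library. Mean level rose with the log of the reads summed over positions, where a read counts at each position it covers. The r was 0.682 (p = 0.00028, adjusted p = 0.00112) and rho 0.605 (p = 0.00204, adjusted p = 0.00816, permutation tests, n = 24, 4 relations). Without the 2 libraries farthest from the median r was 0.635. Within the 11 libraries r was 0.746 (p = 0.00812, permutation) with rho 0.664 (p = 0.0309). Within the 13 libraries r was 0.582 (p = 0.0392) with rho 0.236 (p = 0.434), and r was −0.0803 without the 2 farthest libraries, so the relation rests on those libraries there. With the number of positions at 10 reads, r was 0.544 (p = 0.00545, adjusted p = 0.0109) and rho 0.486 (p = 0.0168, adjusted p = 0.0335), and r was 0.434 without the 2 farthest libraries. At a minimum of 5 reads this r was 0.448 (p = 0.0281, adjusted p = 0.0562), no longer past the threshold after adjustment. Within the sets this r was 0.473 in the 11 libraries (p = 0.141; rho = 0.427, p = 0.19) and 0.644 in the 13 (p = 0.0179; rho = 0.516, p = 0.0733), where r was 0.0992 without the 2 farthest. Over positions measured in every library, r was 0.0108 with reads (p = 0.96, adjusted p = 0.96; rho = −0.0487, p = 0.822) and −0.347 with the number of positions (p = 0.0979, adjusted p = 0.131; rho = −0.39, p = 0.0601). Within the 11 libraries these r were 0.11 (rho = −0.0455) and −0.273 (rho = −0.436), and within the 13 they were 0.0442 (rho = −0.137) and 0.0708 (rho = −0.0165), with permutation p-values of 0.182 or more.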

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

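The splits by set of libraries, the interval of the ratio, the shift expected at intermediate reads and the comparison with the other mitochondrial cytosines were chosen after the values had been seen. Mitochondrial DNA, which no comparison of the report uses, was set against the limit that a count of 0 allows, 0.0019%, since there were no control samples of another kind. Over 12 positions, 2907 of 157980 cytosine calls, or 1.84%, were methylated. The 2907 was rebuilt from whole percents, which allow several counts of methylated reads at deep positions, so it is approximate. The limit of 0.0019% lies below what whole percents resolve. These calls lie on 41040 reads, counted once for each set of cytosines read together, so calls on 1 read are not independent. Libraries ranged from 0% to 3.35%, where 0% can be a small level rounded down. The limit leaves out background from conversion and calling. The 6 cytosines known not to come first in their reads lay at 0.762%, and second cytosines in low nuclear reads at 1.10%. The mitochondrial levels come from whole percents, which are coarser than this gap, so which is lower is not settled. Methylation of mitochondrial DNA above background was thus not shown.

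What stood out was the first cytosine of the read, at 5.14% over 2 positions where the strand shows the order; the ratio of the 6 others to it, 0.148, goes against incomplete conversion along the whole read as the cause. Nuclear reads with low later cytosines also showed an excess at the first cytosine, of at least 1.02 points in each library. This goes against nuclear copies of mitochondrial DNA, unless the classing of reads gives all of it. Over all libraries the nuclear excess correlated with the level of the mitochondrial first cytosines, at r = 0.888 (rho = 0.877, permutation tests, adjusted p = 6e-05 for r and 0.00012 for rho). Within the 13 libraries with the larger drop r was 0.669 (permutation p = 0.00941), and within the 11 others it was 0.318 (p = 0.341). How much the classing adds is not settled by these values. The first cytosine lies farther than the second from the cytosines that class the read. That distance can add to the excess, and to the deficit and shift below, by an amount that was not tested. Miscalling of the first base in both directions would lower the first cytosine in highly methylated reads, and the ratio of that deficit to the excess was 0.239 over all libraries (95% bootstrap interval over libraries 0.118 to 0.41), around the bound of 0.25 set in advance, so miscalling stays open there. In the 11 libraries with the smaller drop the ratio was −0.0113 (interval −0.0376 to 0.0141), which goes against it. In the 13 others the ratio of 0.769 (interval 0.612 to 0.962) goes with miscalling, but such rates would shift intermediate reads by 0.226 points and the observed shift was −10.2 ± 0.858 points, so it cannot be the whole difference there and stays open; no biological explanation was tested.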

How the results depend on the processing

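Leaving out the first and last cytosines of reads, averaging deviations and removing set means were chosen after seeing the data; the others were planned. The mean level of 23.6% depended on the positions used: it was 26.1% at 5 reads, 19.7% at 20 reads, 31.4% with no minimum, 18.3% from pooled reads, 16.7% over positions in every library and 25.7% without the first and last cytosines. Low, intermediate and high shares were 71.4%, 11.6% and 16.96% at 5 reads, 81.7%, 7.85% and 10.5% at 20 reads, 80.3%, 8.56% and 11.1% over positions in all 24 libraries, 71.6%, 11.5% and 16.9% at 12 or more libraries, and 71.8%, 17.4% and 10.8% with limits of 10% and 90%. Without first and last cytosines 72.8% were low. Pooling weights positions by their reads, with no minimum, and the other settings change which positions count, or the limits; the reason that deeper positions are less methylated was not tested. The density difference stayed between 66.6 and 69.6 points, past its threshold, at 5 and 20 reads and in windows of 1000 bases. Intermediate runs numbered 1787 at 30% to 70%, 355 at 40% to 60%, 1270 at 5 reads, 510 at 20 reads and 515 without first and last cytosines. These settings change the range or the positions used. Variable regions numbered 447 with the binomial null and 95 without the 2 farthest libraries, which lowers the spread by construction; under the other 6 settings they numbered from 191 to 263. The r within 200 bases was 0.34, and 0.213 for pairs over 40 bases apart, which leaves out pairs on 1 read. The strand difference of 8.10 points was 6.95 at 20 reads, where counting error is smaller. The r of mean level with the number of positions was 0.448 at 5 reads (adjusted p = 0.0562), past the threshold no longer, for a cause that was not tested; the other 3 depth relations kept their side of the threshold at 5 and 20 reads, as did this one at 20. Levels of the 30 named regions moved by under 1 SD in 29 regions at 5 reads, 25 of 27 at 20 reads and 28 without first and last cytosines. This bound is wide for the 10 variable regions, chosen for large SDs, the smallest being 20.5 points. Within it, the variable region of chromosome 2 went from 56.0% to 74.4% without first and last cytosines. Planned settings for gene context, gene lists and cell type relations were not run, since no annotation of the build was used.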

Other observations

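The chromosome and chromosome-end comparisons, the gaps within regions, the steps and simulated counting error at single positions, the second axis, the mean level without first and last cytosines and the splits by set were chosen after the data had been seen. CpGs near the long-arm ends of chromosomes were more methylated than the rest. In the last 2 megabases before the last listed position, the mean was 33.2 ± 0.982%, against 19.3 ± 0.761% elsewhere (SD, n = 24), and the end was higher in 24 of 24 libraries (two-sided sign-flip permutation, p = 1e-05, adjusted p = 1e-05, the smallest possible). Within classes of CpG density the difference was 18.6 ± 0.317 points for positions with 4 to 9 CpGs in 200 bases, 8.63 ± 0.225 points with 10 or more and 1.85 ± 0.268 points with 1 to 3, each in 24 of 24 libraries (adjusted p = 1e-05). With each number of CpGs in 200 bases matched, the difference was 11.1 ± 0.178 points (SD, n = 24, higher in 24 of 24, permutation p = 1e-05). The end was higher on 19 of 22 chromosomes, the exceptions being 3, 5 and 19. Variable regions made up 1.29% of the 3633 tested regions at ends and 0.587% of the 38993 elsewhere (Fisher's exact test over regions, which are not independent replicates, odds ratio 2.22, p = 6.16e-06). Among regions of intermediate level the shares were 3.29% and 2.77% (odds ratio 1.19, p = 0.411).

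Chromosomes differed in mean level by more than libraries did. Chromosome 21 had the highest mean, 31.7 ± 0.912% (SD, n = 24), 11.5 points above the other autosomes, and chromosome 3 the lowest, 14.5 ± 0.634%, with a difference of −6.25 points from the others. Each held in 24 of 24 libraries (sign-flip permutation, adjusted p = 1.1e-05 and 2.1e-05 over 22 chromosomes). In CpG-dense positions alone the means were 12.5% and 4.02%, and chromosome 19 had 12.9%.

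Single positions with a large spread between libraries were mostly isolated. Of 1567 positions with an SD of at least 20 points, 680 shared reads with other cytosines in a known order. In 64.6% of these (95% Wilson interval 60.9% to 68.1%) the other cytosines of the same reads had a median SD under 0.5 times theirs, past the 50% set in advance. Any source at 1 cytosine would give this, since ordinary neighbours have small SDs, so isolation alone does not point to sequence variants. Counting error alone gave 0 positions with such an SD in a simulation of the 450852 positions in these reads. Levels on the steps of a variant were seen at 23.2% of the isolated and 3.32% of the other 241 positions, so sequence variants and other sources at 1 cytosine cannot be told apart for most of them. The variable regions rest on at least 5 positions each, and leaving out 2555 variant-like positions left 232 called regions, 229 of them among the 276.

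Among the 276 variable regions, 21 had a gap of at least 15 points between sorted library levels with 2 or more libraries on each side. Levels drawn from normal distributions with the means and SDs of these regions gave 6.79 such regions on average and at most 12 in 100 draws. Normal draws do not match skewed levels, so they cannot tell skew from separate groups of libraries. Whether the gaps follow genotype was not tested.

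Libraries also shared axes of variation over the 74875 intermediate positions. The first axis held 11.3% of the variance and the second 7.25%, where equal shares would give 4.35%. First axes from odd and from even chromosomes correlated by 0.996 over libraries, which goes against a few regions as the source. R squared was 0.0437 with the log of the reads summed over positions, which goes against depth by that measure. For the rank of the submitters' library numbers it was 0.0455, which goes against a steady trend along that order only. A rank does not capture the 4 blocks that the 2 sets form in that order, and r squared with the set was 0.435. An effect of the order in blocks therefore stays open. With the excess at first cytosines r squared was 0.431, between the bounds set in advance (0.391 within the 13 libraries of the larger drop and 0.0185 within the 11 others), so a part for library preparation cannot be told apart from other differences between the sets, although leaving out first and last cytosines left the axis in place (r = 0.9998 with the original axis). No biological explanation, such as the mix of cell types, was tested.

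The second axis had r = 0.577 with the rank of library numbers (p = 0.00365, adjusted p = 0.0109 over 12 relations, rho = 0.59, permutation p = 0.0029), and r = 0.539 without the 2 farthest libraries. Within the 13 libraries r was 0.874 (permutation p = 7e-05) and within the 11 it was 0.139 (p = 0.643). It also went with log reads, at r = 0.479 (p = 0.0184, adjusted p = 0.0442; rho = 0.561, adjusted p = 0.0126), r = 0.507 without the 2 farthest libraries, r = 0.732 within the 13 (p = 0.00333) and r = 0.482 within the 11 (p = 0.13).

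Over all 24 libraries the excess at first cytosines correlated with the mean level over positions measured in every library, at r = 0.80 (rho = 0.82, adjusted p = 6e-05 for r and 0.00012 for rho, r = 0.80 without the 2 farthest libraries), where the sets do not overlap in the excess. It was r = 0.522 within the 13 libraries (permutation p = 0.0702; rho = 0.555, p = 0.0515) and r = 0.246 within the 11 (permutation p = 0.466; rho = 0.255, p = 0.452), neither past 0.05. Part of this relation is built in, since the mean level includes first cytosines. Over 396559 positions without the identified first and last cytosines, r was 0.689 over all libraries (permutation p = 0.00023; rho = 0.751, p = 5e-05), with 0.701 without the 2 farthest. It was 0.383 within the 13 (permutation p = 0.194; rho = 0.412, p = 0.165), where it was 0.678 without the 2 farthest, and 0.114 within the 11 (permutation p = 0.739; rho = 0.218, p = 0.52). First cytosines of reads with no known order remain in that mean. The means over positions measured in every library were 17.2 ± 0.464% in the 11 libraries and 16.2 ± 0.333% in the 13 (SD), a difference that was not tested.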
